A study of Homo sapiens with 9 samples.

How the data were processed

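RNA was sequenced from MDA-MB-231 cells that carried a non-targeting hairpin (shNT) or 1 of 2 hairpins against UGDH (shUGDH-1 and shUGDH-2), with 3 libraries per hairpin and 9 in all. Per the labels' protocols, cells were transduced with lentivirus from pGIPZ, RNA was extracted with an RNeasy kit, libraries were made with the NuGen Ovation Universal Plus mRNA-Seq kit and sequenced as read pairs on an Illumina NextSeq instrument. The deposited count table holds raw read counts per gene for each library, with no normalization by the authors visible in the values, which are whole numbers with sums that differ between libraries. The genome build hg19 and the tools STAR, DESeq and DESeq2 are named in the submitters' processing notes. Their versions, the annotation, the counting tool and its use of strand are not given in the sources used here. The authors' deposited tables for each UGDH hairpin against shNT give, per the file headers, a mean signal over libraries (baseMean), a log2 fold change with its standard error, a p-value and an adjusted p-value. These tables were used only for a comparison of calls and of the UGDH fold changes.

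Genes were taken by symbol as the count table gives them. Of 23710 entries, 28 carried symbols that had been converted to dates, 4 of them with a repeated name, and these were kept in the fit without a gene name. They held 0.232% of the counts. Libraries held 9249738 to 13328002 counts, and pairs of libraries within a group differed by 1.2 to 1.91 times the variance of counting alone. The pairs of shNT replicate 1 with replicates 2 and 3 gave the highest values, 1.91 and 1.87. All other pairs lay between 1.2 and 1.47. Genes with low counts were removed with edgeR's filterByExpr on the 3 groups, which left 12546 genes and 99.93% of the counts.

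Before the data were examined, the following choices were made: the fit, the threshold, the alternatives, the gene lists and the rule for naming genes. Counts were normalized by TMM (factors 0.997 to 1.003) and fitted with edgeR's robust quasi-likelihood method over all 9 libraries with a mean per group, which left 6 residual degrees of freedom and a common biological coefficient of variation of 0.0202. Each UGDH hairpin was tested against shNT, and shUGDH-2 against shUGDH-1, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05, with no minimum fold change. Levels are given as CPM (edgeR's counts scaled to a common library size), as mean and SD of 3 libraries. Genes called with both hairpins were the same-direction intersection of both sets. As both contrasts use the same controls, chance overlap and covariance were taken from 40 simulations of unchanged groups against shared controls, beside the overlap of independent lists.

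In all, 28 gene lists were fixed. They cover UDP-sugar metabolism, hyaluronan, sulfated glycosaminoglycan synthesis, proteoglycan cores, UDP-glucuronosyltransferases, mesenchymal and epithelial genes, matrix and adhesion, replication, mitosis, interferon-stimulated genes, NF-kB targets, ATF4 targets, endoplasmic reticulum chaperones, glycolysis and hypoxia, sterol and fatty acid synthesis, the respiratory chain, NRF2 targets, p53 targets, YAP and SRF targets, TGF-beta targets, lysosome and autophagy, ribosomal proteins, markers of luminal breast, leukocyte and fibroblast cells, and histone and mitochondrially encoded genes as signs of RNA quality. The 26 lists with at least 5 tested members were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, with Benjamini-Hochberg adjustment over lists within a contrast. Members that rose, fell or did not pass were counted over all genes tested and adjusted over the list alone.

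The rule for naming genes took UGDH; for each hairpin the 6 higher and 6 lower genes with the largest fold change among those that passed, with a mean of at least 5 CPM in the higher group, a named symbol and no overlap between groups; for both hairpins the 10 higher and 10 lower genes ranked by the smaller fold change under the same conditions; up to 4 members of each list with a mean of at least 1 CPM, those that passed with both hairpins before those that passed with 1; HAS2, HAS3, CD44, HMMR, UGP2, UXS1, SNAI1, VIM and CDH1 whatever their result; and the 5 genes highest and 5 lowest between the hairpins. It named 130 tested genes. COBL was named after its values were seen. Sets of LXR targets, AHR and its targets and MHC class II genes were chosen after the named genes had been seen.

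Hairpin sequences from the labels were matched to GENCODE transcripts in GRCh38, a build other than the authors' hg19, and no coordinate was converted. For seed matches, the fold changes of 11203 genes with a 3′ UTR of at least 50 bases were regressed on the presence of each of 16384 heptamers, with UTR length, UTR base composition and expression as covariates. GC content and transcript length were known for 11627 of the 12546 genes (92.7%), and the check of them is void for respiratory chain genes, where 78.8% had a value.

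The fit was tested on counts simulated from the real means and library sizes and edgeR's own dispersions, with each gene drawn independently. For shUGDH-1 against shNT it recovered 38%, 80%, 72% and 98% of genes changed by 1.15-fold, 1.3-fold, 1.5-fold and 2-fold, with 5.5% of calls false, and for shUGDH-2 against shNT 44%, 68%, 90% and 93.9%, with 4.5% false. A planted list shift of 0.15 on the log2 scale was called in both comparisons, with 1 and 0 of 25 other lists called. As the simulated genes were uncorrelated, this does not test the preset correlation. In the real data the estimated correlation was 0.163 for ribosomal protein genes and 0.182 for luminal markers. In the heptamer test, 3 of 3 planted heptamers ranked lowest, each with a fall of 0.1 on the log2 scale. Smaller falls, such as those found here, were not planted. Alternatives were RLE size factors, no filter, DESeq2, limma-voom, only the 2 groups compared, a replicate block, an adjusted p under 0.01, a minimum absolute log2 fold change of 1, a test against a 1.2-fold change, and omission of each library in turn. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.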

Results

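Gene expression was measured by RNA sequencing in MDA-MB-231, an established human triple-negative breast cancer cell line, after lentiviral transduction with a pGIPZ vector that expressed 1 of 3 short hairpin RNAs. The hairpins were a non-targeting control (shNT) and 2 independent hairpins against UGDH (shUGDH-1 and shUGDH-2), with 3 libraries each. UGDH encodes UDP-glucose 6-dehydrogenase, the enzyme that oxidises UDP-glucose to UDP-glucuronate, which cells use to build hyaluronan and the sulfated glycosaminoglycans and to glucuronidate small molecules. The design addresses which transcripts change when this enzyme is depleted, and whether both hairpins give the change. The 9 libraries held 9249738 to 13328002 counts assigned to genes, with the lowest total in replicate 3 of shUGDH-1, and 14899 to 15278 genes had a count. Per the labels, the cells were grown as biological replicates. Whether each replicate was transduced separately is not stated, so p-values measure the spread between these libraries.

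UGDH transcript was lower in every knockdown library than in every control library. It stood at 52.95 ± 2.67 CPM (SD, n = 3) with shNT, at 7.65 ± 0.37 CPM (SD, n = 3) with shUGDH-1 and at 7.17 ± 0.80 CPM (SD, n = 3) with shUGDH-2. The raw counts were 690, 654 and 590 with shNT, 99, 97 and 74 with shUGDH-1 and 96, 86 and 84 with shUGDH-2. The log2 fold change was -2.80 (SE 0.08, adjusted p = 3.9e-36) with shUGDH-1 and -2.89 (SE 0.08, adjusted p = 1.2e-36) with shUGDH-2, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These leave 14.4% and 13.5% of the control level. Remaining UGDH differed between the hairpins by a log2 value of -0.09 (SE 0.13, adjusted p = 0.74, same test). Both 19-base guide sequences in the labels, TTGCATCAAATATGCGACG for shUGDH-1 and ATATACTTCAGATCTGCTG for shUGDH-2, are antisense to the UGDH mRNA. In GRCh38 they match exon 4 of transcript ENST00000316423.10, on the minus strand of chromosome 4, at positions 39510687 to 39510705 and 39510800 to 39510818, within the coding sequence. The control sequence, ATCTCGCTTGGGCGAGAGTAAG, matched no UGDH transcript.

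**Figure D1:**
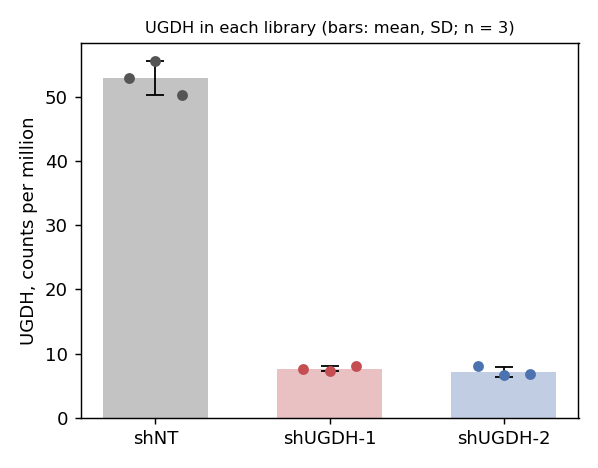
UGDH in CPM (vertical axis, from 0) in each library (points), with bars and error bars for the mean and SD of the 3 libraries of each hairpin (horizontal axis). The 6 knockdown libraries lie between 6.62 and 8.09 CPM and the 3 control libraries between 50.3 and 55.6 CPM.

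With shUGDH-1, the genes that rose furthest, among those with a mean of at least 5 CPM in the higher group and no overlap between groups, were PAPPA, LPL, LIPG, COL4A4, INHBA and SYNDIG1. PAPPA, a protease that cleaves insulin-like growth factor binding proteins, went from 3.37 ± 0.30 to 22.7 ± 1.36 CPM (SD, n = 3), 6.7-fold. LPL, lipoprotein lipase, rose 5.25-fold, LIPG, endothelial lipase, 4.06-fold, and INHBA, a subunit of the growth factor activin A, 3.25-fold. The type IV collagen gene COL4A4 rose 3.49-fold and SYNDIG1, a synaptic membrane protein gene, 2.9-fold. After UGDH, the genes that fell furthest under the same conditions were MED24, a subunit of the Mediator complex of transcription, from 109 ± 1.75 to 43.5 ± 3.23 CPM (SD, n = 3), KYNU, which encodes the tryptophan-degrading enzyme kynureninase, EGF, TMEM64 and ABHD16B, with log2 fold changes of -1.33, -0.94, -0.93, -0.86 and -0.85. The largest adjusted p among these 12 genes was 0.00018, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 12546 genes tested, 1318 rose and 1287 fell. Most changes were small. The median absolute log2 fold change of those that passed was 0.20, and 52 genes rose and 12 fell by 2-fold or more.

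Among the gene lists fixed beforehand, sterol and fatty acid synthesis showed the highest median with shUGDH-1, with 23 of its 30 tested members up, 1 down and 6 not passing (24 up and 1 down when adjusted over the list alone). SCD, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, went from 310 ± 7.52 to 759 ± 10.5 CPM (SD, n = 3), and INSIG1, a sterol-regulated retention protein of the endoplasmic reticulum, rose 1.97-fold. The fatty acid desaturase FADS2 rose 1.85-fold and DHCR7, the last enzyme of one route to cholesterol, 1.55-fold. Epithelial junction and keratin genes rose in 15 of 24 cases and fell in none (18 and 0 adjusted over the list alone), among them SPINT1, a membrane inhibitor of serine proteases, at 2.47-fold, its target protease ST14 at 1.48-fold, the tight junction gene OCLN at 1.92-fold and JUP, plakoglobin, at 1.29-fold. Luminal breast markers, a list that shares 4 members with the epithelial list, moved with them. Of 9 tested, 5 rose and none fell (6 and 0 adjusted over the list alone), with the keratins KRT19, KRT8 and KRT18 at 1.4-fold, 1.32-fold and 1.26-fold. NRF2 antioxidant targets, which include UGDH itself, fell in 12 of 27 cases and rose in 1 (13 and 1 adjusted over the list alone). SLC7A11, which imports cystine, fell by 0.77 on the log2 scale. The aldo-keto reductase genes AKR1C1 and AKR1C3 fell by 0.95 and 0.67, and as close paralogs they can share reads, so the split between them is uncertain. AKR1C1 was low, at 2.08 CPM with shNT and 1.09 CPM with shUGDH-1, and its log2 fold change had an SE of 0.29. SPINT1 and OCLN were also low with shNT, at 2.1 and 4.1 CPM.

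By camera with a preset correlation of 0.01, the adjusted p with shUGDH-1 was 7.85e-34 for sterol and fatty acid synthesis, 1.7e-16 for the epithelial list, 1.3e-08 for luminal markers and 9.4e-11 for NRF2 targets, and these 4 calls held with an estimated correlation (0.00021, 0.0034, 0.033 and 0.0034). Without UGDH, the NRF2 list kept an adjusted p of 1.3e-08 (0.0052 with an estimated correlation). Proteoglycan core proteins rose in 10 of 20 cases and fell in 3, in the same numbers when adjusted over the list alone (adjusted p = 0.000175 by camera, 0.033 with an estimated correlation), with HSPG2, perlecan, at 1.26-fold and COL18A1, a basement membrane collagen, at 1.17-fold. Integrins, laminins and matrix proteases rose in 15 of 32 cases and fell in 6 (17 and 6 adjusted over the list alone; adjusted p = 0.00066 by camera, 0.033 with an estimated correlation), with MMP15 at 1.41-fold and the laminin gene LAMA5 at 1.19-fold. Removal of the trend with GC content, transcript length and expression took the median of the matrix list from 0.087 to 0.055. A further 3 lists passed only with the preset correlation. Ribosomal protein genes fell in 24 of 72 cases and rose in 2 (26 and 2 adjusted over the list alone; adjusted p = 5.8e-06, and 0.32 with an estimated correlation). Glycolysis and hypoxia genes rose in 10 of 37 cases and fell in 1 (12 and 2 adjusted over the list alone; adjusted p = 0.0042, and 0.077 with an estimated correlation), among them the carbonic anhydrase gene CA12 at 1.56-fold. YAP and SRF targets rose in 11 of 36 cases and fell in 3 (13 and 4 adjusted over the list alone; adjusted p = 0.0097, and 0.17 with an estimated correlation), among them EGR1 at 1.29-fold. Removal of the same trend took their median from 0.028 to 0.003.

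With shUGDH-2, the genes that rose furthest, again with at least 5 CPM and no overlap, were LCN2, LIPG, PDZK1IP1, INHBA, C3 and TFAP2C. LCN2, the iron-siderophore carrier lipocalin-2, went from 3.88 ± 0.53 to 14.8 ± 0.73 CPM (SD, n = 3), 3.83-fold, and the complement gene C3 from 17.4 ± 1.35 to 45.6 ± 3.40 CPM (SD, n = 3), 2.62-fold. LIPG rose 3.25-fold, PDZK1IP1 2.75-fold, INHBA 2.68-fold and the transcription factor gene TFAP2C 2.34-fold. After UGDH, the genes that fell furthest under these conditions were TIMP3, an inhibitor of matrix metalloproteases, at -0.78 on the log2 scale, AKR1C3 at -0.76, the type I collagen gene COL1A2 at -0.70, CFP, which encodes the complement factor properdin, at -0.63 and G0S2, an inhibitor of triglyceride lipase, at -0.62. The largest adjusted p among these 12 genes was 0.0036, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 12546 genes, 1009 rose and 855 fell, with a median absolute log2 fold change of 0.18, and 31 rose and 5 fell by 2-fold or more. Without replicate 1 of shUGDH-2, 496 genes fell in place of 855.

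NF-kB targets and secreted inflammatory factors rose with shUGDH-2 in 19 of 35 cases and fell in 3 (21 and 4 adjusted over the list alone), among them the chemokine gene CXCL1 at 1.4-fold and the cytokine gene IL1B at 1.45-fold. The call had an adjusted p of 5.8e-15 by camera and 0.0045 with an estimated correlation. Sterol and fatty acid synthesis genes rose in 19 of 30 cases and fell in 1 (21 and 1 adjusted over the list alone; adjusted p = 2.8e-33 by camera, 0.00022 with an estimated correlation), with SCD at 2.28-fold and INSIG1 at 1.82-fold. Epithelial genes rose in 11 of 24 cases and fell in none (11 and 1 adjusted over the list alone; adjusted p = 8.89e-08 by camera, 0.0175 with an estimated correlation), beside luminal markers at 6 of 9 up and none down, the same with adjustment over the list alone (adjusted p = 1.2e-06 by camera, 0.040 with an estimated correlation). NRF2 targets fell in 9 of 27 cases and rose in 3 (9 and 4 adjusted over the list alone; adjusted p = 2.6e-06 by camera, 0.017 with an estimated correlation), and the list without UGDH kept an adjusted p of 0.00021 by camera (0.030 with an estimated correlation). Proteoglycan cores rose in 6 of 20 cases and fell in 3, also over the list alone (adjusted p = 0.00022 by camera, 0.032 with an estimated correlation), with the syndecan gene SDC4 at 1.24-fold. After removal of the trend with GC content, transcript length and expression, the median of the proteoglycan list with shUGDH-2 went from 0.09 to 0.003 on the log2 scale. Chaperones and unfolded protein response genes of the endoplasmic reticulum rose in 11 of 37 cases and fell in 1, also over the list alone (adjusted p = 0.0017 by camera, 0.031 with an estimated correlation), with HERPUD1 at 1.2-fold and HYOU1 at 1.11-fold.

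Replication genes fell with shUGDH-2 in 8 of 46 cases and rose in none (10 and 0 adjusted over the list alone; adjusted p = 0.0018 by camera, 0.031 with an estimated correlation), and mitotic genes fell in 10 of 48 and rose in 1 (19 and 2 adjusted over the list alone; adjusted p = 0.00021 by camera, 0.034 with an estimated correlation). Their median log2 fold changes were both -0.05, and after removal of the trend with GC content, transcript length and expression -0.06 for replication and -0.028 for mitosis. CCNE1, cyclin E1, stood at -0.29 and CCNA2, cyclin A2, at -0.20, whereas FOXM1, a transcription factor of mitotic genes, rose 1.08-fold. Ribosomal protein genes fell in 33 of 72 cases and rose in none (40 and 0 adjusted over the list alone; adjusted p = 6.4e-14 by camera, and 0.073 with an estimated correlation), with RPS18 at -0.22 and RPS21 at -0.15 on the log2 scale. These genes have many processed pseudogenes, so their counts are uncertain. Removal of the same trend took their median from -0.06 to -0.04 with shUGDH-2 and from -0.04 to -0.02 with shUGDH-1. Nuclear-encoded respiratory chain genes fell in 5 of 52 cases and rose in none, also over the list alone (adjusted p = 0.014 by camera, and 0.15 with an estimated correlation), among them SDHD at -0.25. Mesenchymal genes rose in 10 of 36 cases and fell in 4 (10 and 5 adjusted over the list alone; adjusted p = 0.044 by camera, and 0.18 with an estimated correlation), with FBN1, fibrillin-1, at 1.26-fold and FN1, fibronectin, at 1.18-fold. TNC and COL1A2 of this list fell, at -0.23 and -0.70 on the log2 scale. The list's median was 0.019, and -0.001 without replicate 1 of shUGDH-2. It was 0.030 without replicate 1 of shNT, 0.032 without replicate 3 of shUGDH-2 and 0.034 with only the 2 groups compared.

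**Figure D2:**
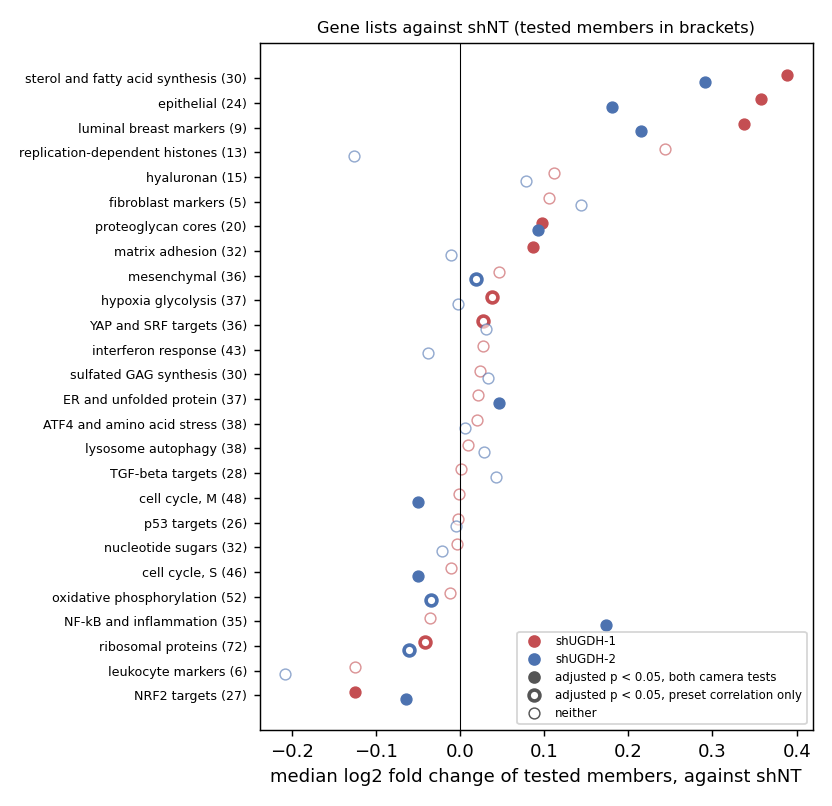
Median log2 fold change against shNT (horizontal axis) of the tested members of each gene list (vertical axis, number of tested members in brackets), with shUGDH-1 in red and shUGDH-2 in blue. Filled points have an adjusted p under 0.05 by camera with both the preset and the estimated correlation, thick rings with the preset correlation only, and thin rings with neither. Sterol and fatty acid synthesis lies highest with both hairpins, at medians of 0.39 and 0.29.

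With both hairpins in the same direction, 592 genes rose and 453 fell. Ranked by the smaller of the fold changes among genes with at least 5 CPM in the higher group of each contrast and no overlap, LIPG led the rise, followed by INHBA, SCD, TFAP2C, CELF2, which encodes an RNA-binding protein, and PAPPA. Next came the lactate and pyruvate transporter gene SLC16A7, NRP2, a coreceptor for semaphorins and vascular endothelial growth factors, INSIG1 and HHIP, an inhibitor of hedgehog signalling. SCD had the smallest adjusted p of these with either hairpin, 1.2e-49 and 1.3e-47 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at log2 fold changes of 1.29 (SE 0.02) and 1.19 (SE 0.02). UGDH led the fall under the same conditions. It was followed by AKR1C3, G0S2, at 279 ± 8.43 CPM with shNT against 164 ± 5.77 and 182 ± 4.83 CPM (SD, n = 3), the cytochrome P450 gene CYP1A1 at -0.59 with each hairpin, ABHD16B, CHIC1, the serine protease gene HTRA3, CYP1B1 at -0.63 and -0.43, SLC7A11 at -0.77 and -0.40, and ZNF780B. Of the lists, sterol and fatty acid synthesis had 18 of 30 members up with both, the epithelial list 10 of 24 and luminal markers 4 of 9. NRF2 targets had 9 of 27 down with both, UGDH included, and ribosomal protein genes 20 of 72. Without replicate 1 of shNT the number that fell with both was 299, and without replicate 1 of shUGDH-2 it was 268. With DESeq2, 310 genes rose and 197 fell with both.

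Both contrasts use the same 3 control libraries, which alone makes fold changes alike. In 40 simulations of unchanged groups against shared controls, a mean of 0.07 genes rose with both and 0.07 fell with both. These groups held no change, so few genes could pass and the low overlap was fixed in advance. Independent lists of the observed lengths would share 106 and 87.7 genes. With the 3 groups kept whole but another group as control, 791 genes passed the same way, against 1045 with shNT as control. The covariance of the log2 fold changes was 0.0301, against 0.0097 in the simulations, a difference of 0.0204. Their correlation across genes, which are not independent replicates, was 0.608 against a simulated 0.50. A split of the 3 controls would leave 1 library on a side and was not made, so part of the excess over either value may come from the shared controls.

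**Figure D3:**
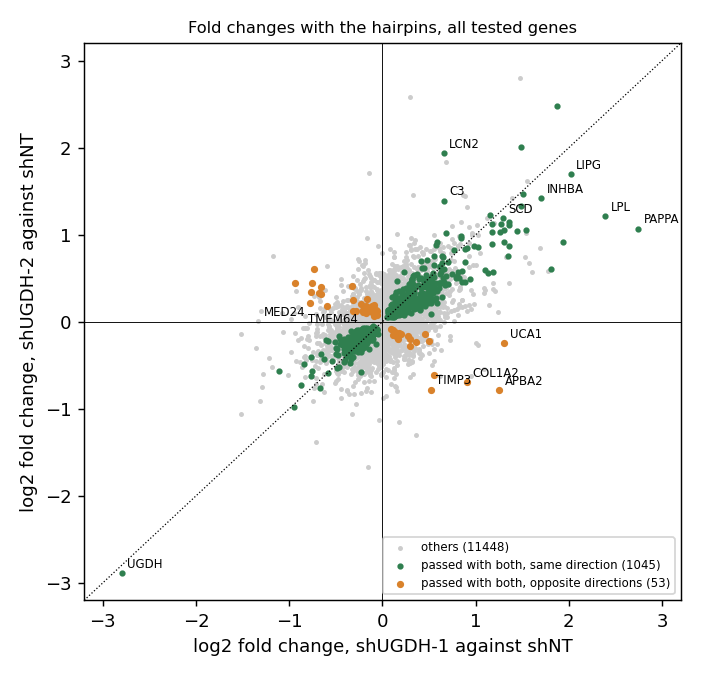
Log2 fold change against shNT of each tested gene with shUGDH-1 (horizontal axis) and shUGDH-2 (vertical axis). Green points passed with both hairpins in the same direction (1045 genes), orange points in opposite directions (53 genes), grey points are the others, and the dotted line marks equal change. UGDH lies at the lower left, and 1 gene with very few counts, COBL, lies outside the axes.

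Genes of UDP-sugar metabolism and of hyaluronan and glycosaminoglycan synthesis, the routes that supply or use the product of UGDH, were not called as lists by camera with either hairpin. Of 32 tested genes for UDP-sugar interconversion and transport, 3 rose and 5 fell with shUGDH-1 and 2 rose and 6 fell with shUGDH-2 (3 and 6, then 2 and 6, adjusted over the list alone). The hexokinase gene HK2 stood at -0.21 and -0.15 and the glycogen synthase gene GYS1 at 0.19 and 0.14 on the log2 scale, and all 4 changes passed. Of 15 hyaluronan genes, 4 rose with shUGDH-1 and 1 with shUGDH-2, and none fell (4 up and 0 down, then 2 up and 1 down, adjusted over the list alone). KIAA1199, a hyaluronan-degrading protein also called CEMIP, rose 1.19-fold and 1.13-fold. Of 30 genes for the synthesis of sulfated chains, 5 and 9 rose and 2 fell with each hairpin (7 and 11 up, 2 down with each, adjusted over the list alone), among them UST, a uronyl sulfotransferase, at 0.29 and 0.27 on the log2 scale and the xylosyltransferase gene XYLT2 at 0.26 and 0.21, while FAM20B, a xylose kinase of the chain linker, stood at -0.16 and -0.20. By camera the adjusted p with shUGDH-1 and shUGDH-2 was 0.65 and 0.12 for UDP-sugar genes, 0.056 and 0.31 for hyaluronan genes and 0.20 and 0.056 for sulfated chain synthesis. By fry, which tests whether a list's genes move one way without comparing them with other genes, hyaluronan genes had an adjusted p of 0.0037 and 0.062, sulfated chain synthesis 0.0056 and 0.0042, and UDP-sugar genes 0.17 and 0.019. Removal of the trend with GC content, transcript length and expression took the sulfated chain median from 0.024 to 0.013 with shUGDH-1. With shUGDH-2 it went from 0.033 to -0.004. No UDP-glucuronosyltransferase gene of the 18 listed had enough counts to be tested.

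Among the genes reported whatever their result, the hyaluronan synthase HAS2 stood at 1.33 ± 0.44 CPM with shNT and at 1.92 ± 0.59 and 1.82 ± 0.36 CPM with shUGDH-1 and shUGDH-2 (SD, n = 3), with adjusted p of 0.21 and 0.33 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. HAS3 had group means of 0.933 to 1.44 CPM and did not pass with either hairpin. The hyaluronan receptor CD44, at 1132 CPM with shNT, had log2 fold changes of -0.03 (SE 0.02) and -0.02 (SE 0.02). HMMR, another receptor, had -0.08 (SE 0.09) and -0.23 (SE 0.09), UGP2, which makes UDP-glucose, -0.06 (SE 0.05) and 0.03 (SE 0.05), and UXS1, which uses UDP-glucuronate to make UDP-xylose, 0.00 (SE 0.03) and 0.04 (SE 0.03). The mesenchymal transcription factor SNAI1 had -0.12 (SE 0.10) and 0.13 (SE 0.09). None of these 5 passed with either hairpin. Vimentin, VIM, rose 1.13-fold with shUGDH-1 (adjusted p = 1.2e-13, same test) and had a log2 fold change of -0.04 with shUGDH-2 (adjusted p = 0.087, same test). CDH1, E-cadherin, with 59 counts over the 9 libraries, and HAS1, with 14, were too low to be tested.

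The other lists passed with neither hairpin by camera. Interferon-stimulated genes, also induced by double-stranded RNA, rose in 6 and fell in 4 of 43 cases with shUGDH-1 and rose in 2 and fell in 9 with shUGDH-2 (6 and 5, then 3 and 10, adjusted over the list alone). ATF4 and amino acid stress genes rose in 7 and fell in 7 of 38 cases with shUGDH-1 and rose in 2 and fell in 5 with shUGDH-2, with the same counts over the list alone. The p53 targets rose in 1 and 3 and fell in 1 and 1 of 26, again with the same counts. TGF-beta targets rose in 4 and fell in 3 of 28 cases, then rose in 7 and fell in 3 (4 and 3, then 7 and 4, adjusted over the list alone). Lysosomal genes rose in 7 and fell in 4 of 38, then rose in 7 and fell in 3 (7 and 4, then 8 and 4, adjusted over the list alone). Leukocyte markers fell in 3 and 2 of 6 cases and rose in none (3 down and 1 up, then 2 down and 0 up, adjusted over the list alone), among them CD68 at -0.16 and -0.12. Fibroblast markers rose in 1 of 5 cases with each hairpin and fell in 1 with shUGDH-2. Replication-dependent histone genes, a sign of RNA quality in poly(A) libraries, rose in 1 of 13 cases with shUGDH-1 and fell in 1 with shUGDH-2, with the same counts over the list alone for both lists. Mitochondrially encoded genes had no tested member. NF-kB targets with shUGDH-1 (7 up and 8 down of 35, and 8 and 9 over the list alone) and mesenchymal genes with shUGDH-1 (11 up and 7 down of 36, also over the list alone) did not pass. Neither did the matrix list with shUGDH-2 (11 up and 6 down of 32, and 12 and 8 over the list alone), glycolysis and hypoxia genes with shUGDH-2 (5 up and 7 down of 37, and 6 and 8 over the list alone) and YAP and SRF targets with shUGDH-2 (9 up and 5 down of 36, and 9 and 7 over the list alone). With shUGDH-1, replication genes rose in 4 and fell in 8 of 46 cases, also over the list alone, and mitotic genes rose in 3 and fell in 7 of 48 (4 and 7 over the list alone). Endoplasmic reticulum genes rose in 6 and fell in 4 of 37 with shUGDH-1, also over the list alone, and respiratory chain genes rose in 4 and fell in 2 of 52 (1 and 2 over the list alone), and none of these 4 lists passed. The median and mean had opposite signs for NF-kB targets (-0.04 and 0.04) and ATF4 genes (0.02 and -0.002) with shUGDH-1 and for the matrix list (-0.01 and 0.02) and p53 targets (-0.005 and 0.005) with shUGDH-2. ATF4 genes with shUGDH-2 had a median and mean above 0 and a camera direction below it, and ATF4 genes with shUGDH-1 a camera direction above 0.

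The hairpins were also compared directly, which leaves out the means of the shared controls, though the control libraries still entered the filter and the estimated spread. Among genes with at least 5 CPM in the higher group and no overlap, KYNU, MED24, LCN2, HLA-DRB5 and PDZK1IP1 were furthest higher with shUGDH-2, at log2 differences of 1.39, 1.34, 1.28, 1.21 and 1.14. APBA2, PAPPA, COL1A2, the long noncoding RNA gene UCA1 and TIMP3 were furthest lower, at -2.04, -1.67, -1.60, -1.56 and -1.30. UCA1 went from 91.7 ± 2.35 CPM with shNT to 227 ± 1.65 CPM with shUGDH-1 and 77.2 ± 2.19 CPM with shUGDH-2 (SD, n = 3), and its difference between the hairpins had the smallest adjusted p of the 10, 1.8e-42, against a largest of 2.2e-06, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MED24 stood at 110 ± 4.07 CPM with shUGDH-2, a log2 fold change of 0.01 (SE 0.04) against shNT. TIMP3, COL1A2, APBA2 and UCA1 rose with shUGDH-1 and fell with shUGDH-2, and KYNU and HLA-DRB5, which shares reads with other HLA-DRB genes, fell with shUGDH-1 and rose with shUGDH-2. Against shNT, the rises with shUGDH-2 had adjusted p of 0.040 for KYNU and 0.030 for HLA-DRB5 by the same test. In the authors' deposited values those rises, and the fall of APBA2 with shUGDH-2, did not reach an adjusted p under 0.05. In all, 672 genes were higher and 691 lower with shUGDH-2, at a median absolute log2 difference of 0.19, and 53 genes passed in opposite directions against shNT. A fit of only the 2 groups compared gave 1606 differing genes in place of 1363, and omission of replicate 1 of shNT gave 1627.

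NF-kB targets were higher with shUGDH-2 than with shUGDH-1 in 20 of 35 cases and lower in 2 (22 and 3 adjusted over the list alone; adjusted p = 2.6e-20 by camera, 0.0036 with an estimated correlation). Epithelial genes were lower in 9 of 24 cases and higher in 1 (11 and 1 adjusted over the list alone; adjusted p = 1.7e-07 by camera, 0.017 with an estimated correlation). Sterol and fatty acid synthesis genes were lower in 9 of 30 and higher in 1 (13 and 1 adjusted over the list alone; adjusted p = 3.9e-05 by camera, 0.017 with an estimated correlation), and glycolysis and hypoxia genes lower in 14 of 37 and higher in 1 (16 and 1 adjusted over the list alone; adjusted p = 1.3e-06 by camera, 0.017 with an estimated correlation). NRF2 targets were higher in 6 of 27 cases and lower in none (7 and 0 adjusted over the list alone; adjusted p = 0.000845 by camera, 0.040 with an estimated correlation). A further 8 lists passed with the preset correlation only, with adjusted p between 0.10 and 0.21 with an estimated correlation. Luminal markers, the matrix list, both cell cycle lists, interferon-stimulated genes, respiratory chain genes and histone genes were lower with shUGDH-2, and endoplasmic reticulum genes were higher. The calls of the matrix, cell cycle, respiratory chain, histone and endoplasmic reticulum lists each ended without 1 or more of the libraries of the hairpins, and the histone median took the opposite sign without replicate 3 of shUGDH-2. The median and mean of mesenchymal, YAP and SRF, ATF4, p53 and fibroblast lists had opposite signs between the hairpins, and none of these 5 lists passed.

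The short sequence at the start of a guide can pair with sites in the 3′ UTRs of other transcripts, and such sites were counted in 11203 genes. The test set beforehand took guide positions 2 to 8 and each hairpin against the other. Of all 16384 heptamers, the site ranked 7 from the lowest for shUGDH-1 (statistic -3.44) and 167 for shUGDH-2 (-2.27). Against shNT, the site of these positions ranked 1353 with shUGDH-1 (-1.56) and 127 with shUGDH-2 (-2.81). Where the mature guides start is not given in the sources used here. The sites of positions 1 to 7 were examined against shNT after the results were seen. The site for shUGDH-1, GATGCAA, had the lowest statistic of all heptamers in its contrast, at -5.73. Its 953 carrier genes stood 0.04 lower on the log2 scale after adjustment for UTR length, UTR base composition and expression. The site for shUGDH-2, AGTATAT, had the lowest in its own, at -5.55, with 1703 carrier genes 0.03 lower. In the other hairpin's contrast these sites ranked 10837 and 549. Of the named genes that fell furthest with shUGDH-1, MED24 and TMEM64 carry GATGCAA, and KYNU, EGF and ABHD16B do not, against 8.5% of all genes searched. With shUGDH-2, TIMP3, AKR1C3, COL1A2, CFP and G0S2 do not carry AGTATAT, against 15.2% of all. TMEM64 and KYNU carry it, but with shUGDH-2 TMEM64 did not pass (log2 fold change -0.08) and KYNU rose (0.45). PAPPA, TIMP3 and TMEM64 carry the shUGDH-1 site for positions 2 to 8. With shUGDH-1, PAPPA and TIMP3 rose and TMEM64 fell. In the direct comparison, 17.5% of genes lower with shUGDH-1 and 5.1% of genes higher with it carry GATGCAA. For shUGDH-2 and AGTATAT the shares are 17.7% and 16.4%.

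**Figure D4:**
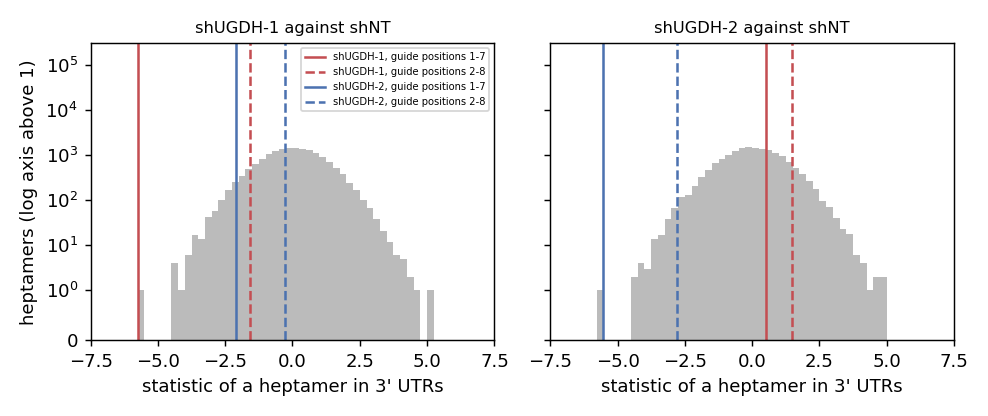
Distribution of the statistic of 16384 heptamers in 3′ UTRs (horizontal axis, negative where carrier genes are lower) as the number of heptamers per bin (vertical axis, logarithmic above 1), for shUGDH-1 (left) and shUGDH-2 (right) against shNT. Red and blue lines mark the sites of shUGDH-1 and shUGDH-2, dashed for guide positions 2 to 8 and solid for positions 1 to 7. Positions 2 to 8 were set beforehand for the comparison between the hairpins, and positions 1 to 7 were examined against shNT afterwards. Each hairpin's own site lies at -1.56 and -2.81 for positions 2 to 8 and at the lowest end, -5.73 and -5.55, for positions 1 to 7.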

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

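The tests of the state of the shNT culture, of loss of UGDH and of unequal loss of UGDH were chosen after the results were seen, as were the ranks of guide positions 1 to 7 against shNT. The list and gene differences below were flagged because the direct test of shUGDH-2 against shUGDH-1 passed, for 49 of 130 named genes (edgeR) and 13 of 26 lists (camera, preset correlation). Ribosomal protein genes did not pass it (adjusted p = 0.059 by camera). Their fall and the rise of sterol genes with both hairpins, and other groupings of the libraries, were examined apart from this rule. With an estimated correlation 5 of the 13 lists passed, those of epithelial genes, NF-kB targets, glycolysis and hypoxia, sterol and fatty acid synthesis, and NRF2 targets, and the other 8 had adjusted p from 0.103 to 0.208. Without 1 library the call ended for mitosis (replicates 1 and 2 of shUGDH-1 and of shUGDH-2), replication (replicate 3 of shUGDH-1), chaperones (replicates 2 and 3 of shUGDH-1, replicate 1 of shUGDH-2), matrix (replicate 1 of shUGDH-1), respiratory chain (replicate 3 of shUGDH-1, replicates 2 and 3 of shUGDH-2) and histone genes (replicate 3 of either hairpin), with adjusted p from 0.0544 to 0.156. Ribosomal protein genes passed without replicate 1 of either hairpin. All differences are log2, shUGDH-2 minus shUGDH-1, and for lists the median over tested members.

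Among lists, the difference was -0.21 for epithelial genes, -0.056 for luminal markers, -0.030 for matrix and adhesion, -0.045 for replication, -0.034 for mitosis, -0.11 for interferon-stimulated genes, -0.064 for glycolysis and hypoxia, -0.089 for sterol and fatty acid synthesis, -0.025 for the respiratory chain and -0.17 for histone genes. It was 0.20 for NF-kB targets, 0.026 for endoplasmic reticulum chaperones and 0.054 for NRF2 targets. The histone median was 0.11, of opposite sign, without replicate 3 of shUGDH-2 and between -0.298 and -0.108 where it moved by over 1.5 times otherwise (limma-voom, only the 2 groups compared, or without any 1 of the other 5 libraries of the hairpins). Without 1 library, the NRF2 median was 0.016 (replicate 1 of shUGDH-2), the interferon median was -0.065 and -0.062 (replicate 1 of shUGDH-1, replicate 2 of shUGDH-2), the matrix median -0.018 (replicate 1 of shUGDH-1) and the replication median -0.029 (replicate 3 of shUGDH-1). The luminal median was -0.119 and -0.035 without replicates 1 and 3 of shUGDH-1 and -0.094, -0.029 and -0.093 without replicates 1, 2 and 3 of shUGDH-2, and the respiratory chain median -0.042 and -0.039 without replicate 1 of shUGDH-1 and of shUGDH-2.

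Among genes named for their fold changes, the difference was -1.67 for PAPPA, -1.18 for LPL, -1.20 for COL4A4, 1.34 for MED24, 1.39 for KYNU, 0.78 for TMEM64, 1.28 for LCN2, 1.14 for PDZK1IP1, 0.73 for C3, -1.30 for TIMP3, -1.60 for COL1A2, -0.51 for CFP, 1.21 for HLA-DRB5, -2.04 for APBA2 and -1.56 for UCA1. Of genes that passed with both hairpins, G0S2 differed by 0.15, SCD by -0.10, NRP2 by -0.23, INSIG1 by -0.11, HHIP by -0.59, CYP1B1 by 0.20, SLC7A11 by 0.37 and FADS2 by -0.20. Matrix, junction and hyaluronan genes differed by -0.23 (TMEM2), -0.14 (LAYN), -0.068 (HSPG2), 0.18 (SDC4), -0.13 (COL18A1), -0.21 (FBN1), -0.21 (FN1), 0.28 (TNC), 0.32 (COL1A1), -0.44 (OCLN), 0.18 (JUP), -0.27 (KRT19), -0.24 (KRT8), -0.18 (KRT18) and -0.22 (VIM). Genes of the other lists differed by 0.30 (GINS3), -0.18 (PPP1R15A), -0.35 (CA12), -0.19 (ATP5H), 0.67 (SESN1), 0.62 (GDF15), -0.10 (EGR1), 0.083 (ANKRD1), -0.54 (IL11), 0.05 (CTSD) and 0.17 (RPL34).

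Between the hairpins 1363 genes differed, and 53 passed in opposite directions against shNT. Unequal loss of UGDH would move genes the same way with both hairpins to different extents. The 53 genes are the pattern itself and no separate test of this. Remaining UGDH transcript was apart by -0.09 (SE 0.13) on the log2 scale, which argues against a large inequality of transcript loss as their cause. A small inequality lies within this error, and UGDH protein and enzyme activity are not measured by these data. The lower depth of replicate 3 of shUGDH-1 was argued against as the whole cause by the 1066 genes that differed without it. Silencing through the start of the guide may account for part of the difference for shUGDH-1, whose site for positions 2 to 8 ranked 7 from the lowest of 16384 heptamers between the hairpins, though 1353 against shNT, and whose site for positions 1 to 7 ranked 1 between the hairpins. For shUGDH-2 that site ranked 167, outside the lowest 1% that was asked for, and its site for positions 1 to 7 ranked 8, so silencing by this guide stays open.

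Sterol and fatty acid synthesis genes were higher with both hairpins. Removal of the trend with GC content, transcript length and expression left a median of at least 0.294 with each hairpin, and omission of any shNT library a median of at least 0.275, which argues against either as the whole cause. Loss of UGDH, with 18 of 30 members up with both hairpins, and a state of the shNT culture as a whole, with a median of 0.291 with shUGDH-2 beside 0.389 with shUGDH-1, cannot be told apart, since shNT was the only control hairpin. Either may be the cause of the rise that the hairpins share. The list also differed between the hairpins, at a median of -0.089 (adjusted p = 3.9e-05 by camera, 0.017 with an estimated correlation). The shNT means drop out of that comparison, which argues against a state of the shNT culture as the cause of this difference.

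Of 72 ribosomal protein genes, 20 fell with both hairpins, and the list's calls did not hold with an estimated correlation (adjusted p = 0.317 and 0.0731 by camera). Against genes matched on length, GC content and expression their median difference was -0.037 or lower with each hairpin, but the matched genes had a median length of 1782 bases against 1170 for the list, so the match was incomplete and a length or GC trend may remain. The state of the shNT culture, at a median of -0.041 with shUGDH-1 and -0.06 with shUGDH-2, stays open for want of another control hairpin.

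Other groupings of the libraries were counted. For shUGDH-1 against shNT (2605 genes), shUGDH-2 against shNT (1864) and shUGDH-2 against shUGDH-1 (1363), the 10 splits of 6 libraries are too few for a share under 0.05, and the highest other split gave 0, 0 and 2 genes. For genes called the same way with both hairpins, 1 of 60 drawn splits of the 9 libraries, the real one, reached 1045 genes. The highest other, 791, kept the 3 groups whole with another group as control, and the highest that mixed groups gave 496. These counts argue against a random sorting of the libraries as the source of the 1045. They cannot exclude differences between the cultures that are unrelated to UGDH, since all libraries of a group may share them.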

How the results depend on the processing

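No alternative in this part was chosen after the results were seen. No gene call took the opposite direction under any fit or omission compared. The UGDH log2 fold changes against shNT kept their direction and passed under each refit (RLE size factors, no filter, DESeq2, limma-voom, only the 2 groups compared, replicate block) and each omission of a library, and the covariance of the hairpins, which has no test, lay between 0.0273 and 0.0376 in them. RLE size factors, no filter, limma-voom and the fit of only the 2 groups compared kept each of the 7 gene counts within 1.5 times. No scaling moved the median of all genes by as much as 0.01. In simulated data, 80% and 68% of genes changed by 1.3-fold were recovered with shUGDH-1 and shUGDH-2, and 38% and 44% at the smallest change tried, so counts of small changes are incomplete at this depth.

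Counts are given in the order higher and lower with shUGDH-1, higher and lower with shUGDH-2, higher and lower with both, and differing between hairpins, against 1318, 1287, 1009, 855, 592, 453 and 1363. DESeq2 gave 816, 725, 545, 413, 310, 197 and 756, and of its calls 1539 of 1541, 954 of 958 and 754 of 756 were shared in direction for shUGDH-1, shUGDH-2 and between hairpins. The cause was not tested. Stricter settings give fewer genes by construction. An absolute log2 fold change of at least 1 left 52, 12, 31, 5, 20, 1 and 35, and a test against a 1.2-fold change (glmTreat) 149, 35, 62, 9, 37, 6 and 84. An adjusted p under 0.01 left 782 lower with shUGDH-1, 616 higher and 433 lower with shUGDH-2, 352 higher and 204 lower with both, and 838 between hairpins. By fry, which does not compare a list with other genes, 15 and 20 lists passed, against 9 and 12 by camera and 6 and 9 with an estimated correlation.

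With 1 library left out, genes lower with shUGDH-2 ranged from 496 (without replicate 1 of shUGDH-2) to 815, and genes lower with both from 268 (without replicate 1 of shUGDH-2) to 426, with 299 without replicate 1 of shNT. Fewer libraries enter these fits, and why replicate 1 matters most was not tested. Of 388 tests of named genes, DESeq2 left 71 short of the threshold, no filter 4, the replicate block 3, limma-voom 4 with 2 more passing, and the fit of 2 groups 5 with 2 more passing. For lists against shNT, omission of a library ended 2 camera calls and added 9, with 9 to 10 lists called with shUGDH-1 and 11 to 14 with shUGDH-2. For named genes, it left 173 such tests short, with 13 more passing, and 3306 kept their call.

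Libraries of different groups share only a replicate number. With a replicate block the counts were 1298, 1284, 993, 864, 582, 456 and 1326, and no list call changed, against shNT or between the hairpins. Correlations of same-numbered libraries' deviations ran from -0.041 to 0.069, against -0.046 to 0.05 for different numbers. The main fit assumed no pairing. As 6 of 9 libraries correlated best with their own number, a weak pairing cannot be excluded.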

Other observations

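The sets of LXR targets, AHR and its targets and MHC class II genes were chosen after the named genes had been seen, the LXR test before its own values were.

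A rise of sterol synthesis genes may follow from low cell sterol, in which case targets of the sterol-activated receptor LXR would fall. Of 6 tested LXR targets, 3 rose with both hairpins (ABCA1 by 0.45 and 0.48, ABCG1 by 0.85 and 0.98 and LPCAT3 by 0.54 and 0.40 on the log2 scale) and none fell. Their medians were 0.30 with shUGDH-1 and 0.316 with shUGDH-2, which argues against low sterol as the cause as far as these transcripts report it.

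MHC class II genes, whose close paralogs can share reads, moved apart between the hairpins. The set was prompted by HLA-DRB5. Of the 8 other genes in it, 6 fell with shUGDH-1 (log2 fold changes of all 8 from -0.77 to -0.09), 8 rose with shUGDH-2 (0.22 to 0.40) and 8 were higher with shUGDH-2 than with shUGDH-1 (0.37 to 1.12). HLA-DRA stood at 45.7 ± 0.60 CPM with shNT, 29.1 ± 2.62 CPM with shUGDH-1 and 57.0 ± 1.08 CPM with shUGDH-2 (SD, n = 3). CIITA, the transcription factor of the class, had a log2 fold change of -0.15 (adjusted p = 0.212) and 0.31 (adjusted p = 0.00278) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

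A set of the receptor gene AHR and 6 of its targets was prompted by the falls of CYP1A1 and CYP1B1. Of the other genes in it, TIPARP and NQO1 fell with each hairpin, and AHR, AHRR and ALDH3A1 passed with neither.

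In the authors' deposited table for shUGDH-1 against shNT, 1981 genes had an adjusted p under 0.05, and 1967 of them passed here in the same direction. In the authors' deposited table for shUGDH-2 against shNT there were 1254, of which 1244 passed here in the same direction. The authors' deposited tables give UGDH log2 fold changes of -2.68 and -2.75.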
